A study of Saccharomyces cerevisiae with 3 samples.

How the data were processed

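Total RNA of Saccharomyces cerevisiae was measured on 3 two-colour Agilent expression arrays, 1 per genotype. Per the labels, both channels of an array held biological replicates of the same genotype, so that each genotype had 2 channels: replicate 1 in Cy5 and replicate 2 in Cy3. The genotypes were the BMA wild-type strain (WT), a chd1 isw1 double knock-out (DKO) and a chd1 isw1 isw2 triple knock-out (TKO). Cultures grew overnight in YPAD, a rich glucose medium, at 30 °C, and 500 ng of RNA entered each labelling reaction, which ran at 40 °C and was primed by oligo-dT. The labels' protocol text names Cy3 CTP alone, whereas the series describes a two-colour kit, and the culture density at harvest is not stated.

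Per the file headers, the authors scanned the arrays and quantified each spot with Agilent Feature Extraction 10.7.3.1. The raw deposited values are intensity values: the mean brightness of a spot and the median brightness of its local background in each channel. The processed intensity values in the same deposited files were background-subtracted, detrended and dye-normalized within the array by the authors' scanner software. Other deposited columns hold flags of 0 or 1 per spot and channel, for a signal well above background, saturation and non-uniform spots. A further deposited table of the authors holds 4 columns of normalized log10 ratios, per its first line and per its slope of 1.02 to 1.03 against log10 differences of the scanner signals. Over 2697 probes of intensity 500 or more in all channels, each of its columns followed a pair of channels other than the pair that its heading names. The correlation across probes was 0.9975 to 0.9991 for the best pair and -0.657 to 0.326 for the named pair. This table was therefore left out of the comparisons.

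All comparisons were computed from the raw intensities with R 4.3.3 and limma 3.58.1. Background was corrected with normexp (offset 50), arrays were normalized with loess within the array and Aquantile between arrays, and log2 values per channel were taken. Of 15208 gene spots per array, those with a non-uniformity or population flag in either channel were left out (306 to 337 per array), as were 536 control spots. The 2 to 3 spots of a probe were averaged, then the probes of a gene, giving 6256 probes and 6227 genes, of which 28 had at least 2 probes. Genes were tested where a probe was well above background in both channels of at least 1 array, which left 5739. Gene names and chromosomes came from the array annotation, built on genome build sacCer1; 5738 genes matched the names of the reference annotation R64 and 489 did not. Of the genes tested, 134 had a probe annotated to more than 1 gene. For 1 gene, RIM8, probes gave opposite directions more than 2-fold apart. In any channel, 12 probes were saturated.

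One linear model per gene was fitted in limma over all 6 channels with genotype and an additive dye term, followed by eBayes (residual df 2, prior df 3, prior SD 0.219 on the log2 scale). P-values were adjusted by Benjamini-Hochberg over genes within each of the 3 comparisons, with a threshold of 0.05. Each genotype was on a single array, so genotype and array could not be told apart. Values after ± are standard errors of the fitted log2 difference, from n = 2 channels per genotype except where a channel was left out. Where a genotype was not well above background in either channel and the other was in both, a lower limit of the fold was computed. For this limit the dim channels were set to the lowest probe called above background in that channel (log2 6.18 to 6.55) or to their own value if higher, and it is written as at least N-fold.

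Before the data were examined, the comparisons, 39 gene lists, the alternatives and a rule for named genes were fixed. Lists with at least 4 measured members (38) were tested with camera in limma at a preset correlation of 0.01, adjusted over lists, and again with a correlation estimated from the residuals. With a residual df of 2 the latter test could hardly call any list. Its values therefore do not decide whether correlation within lists accounts for a shift. Named genes per comparison were the deleted genes and 5 marker genes, the 8 highest and 8 lowest log2 fold changes among called genes with 1 direction in both dyes, up to 4 called members of each shifted list, up to 2 members of other lists, and the 5 largest values each way where no gene was called. Other genes are said to have been chosen after their values were seen.

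The number of arrays and channels, 3 and 6, limits the precision. Median raw signals were 454.8 to 820 over local backgrounds of 26 to 53. The fit was tested on simulated data with the measured spread: of genes changed by 1, 2 and 4 on the log2 scale, 38.8% to 55.2%, 98.5% and 100% were called, with 8 to 18 false calls among 171 to 183. In the simulated list test the shifted list and 1 of 37 other lists were called. Simulated genes were independent, and any dye effect was the same on all arrays. The simulations thus lacked correlation within lists and the Cy5 minus Cy3 mismatch between DKO and the other genotypes. Their rates may therefore not hold for the measured data. Alternatives covered background correction, normalization within and between arrays, the filter on dim probes, the mean or brightest probe, the dye term, variance moderation, a fold minimum, the 4 channels of a comparison alone, and each channel left out in turn. Further alternatives were chosen after seeing the data: without chromosome VIII genes, without mating genes, and without the DKO Cy3 channel together with chromosome VIII genes. Figures were drawn with Python 3.11.15, matplotlib 3.10.9 and numpy 2.4.6.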

Results

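Chd1, Isw1 and Isw2 are Snf2-related ATPases that space nucleosomes, and the series asks what these enzymes do for nucleosome organization across the yeast genome. Expression of 5739 genes was compared among WT, DKO (chd1 isw1) and TKO (chd1 isw1 isw2) cells, with 2 channels per genotype on 1 array each. Median raw signals over local background were 14 (Cy5) and 31.3 (Cy3) for WT, 9.25 and 17.2 for DKO, and 12.4 and 30.4 for TKO. Between 88.72% and 93.98% of gene spots were well above background in a channel.

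CHD1, ISW1 and ISW2 transcripts were read first, since each label predicts which of them are missing. CHD1 (YER164W, probe on chromosome V at 509597 to 509656) had processed intensities of 1429 and 717.1 in WT and of 6.632 and 8.265 in DKO. In TKO it gave 9.839 in Cy5 and 37.15 in Cy3. ISW2 (YOR304W, XV at 887711 to 887770) gave 1184 and 650.4 in WT, 494.1 and 527.6 in DKO, and 24.03 and 41.2 in TKO. ISW1 (YBR245C, II at 708165 to 708224) gave 3473 and 3215 in WT, 9.587 and 149.3 in TKO, and 6.549 in DKO Cy5. In the channel labelled DKO Cy3, however, ISW1 gave 2191, well above background and close to WT, so that the ISW1 transcript contradicts the label of that channel. In TKO Cy3, CHD1, ISW1 and ISW2 were also well above background, though far below WT, whereas none of them was in TKO Cy5. Every DKO value that combines both channels therefore rests on 1 channel without and 1 channel with ISW1 transcript. TRP1, a tryptophan biosynthesis gene used as a strain marker, gave 940.4 and 51.25 in WT, 6.771 and 8.325 in DKO, and 3837 and 2638 in TKO. The 2 WT channels, labelled as 1 genotype, thus differed in this marker (normalized log2 9.291 in Cy5 and 6.465 in Cy3). TRP1 values against WT average these channels, and the cause of the difference was not tested.

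**Figure D1:**
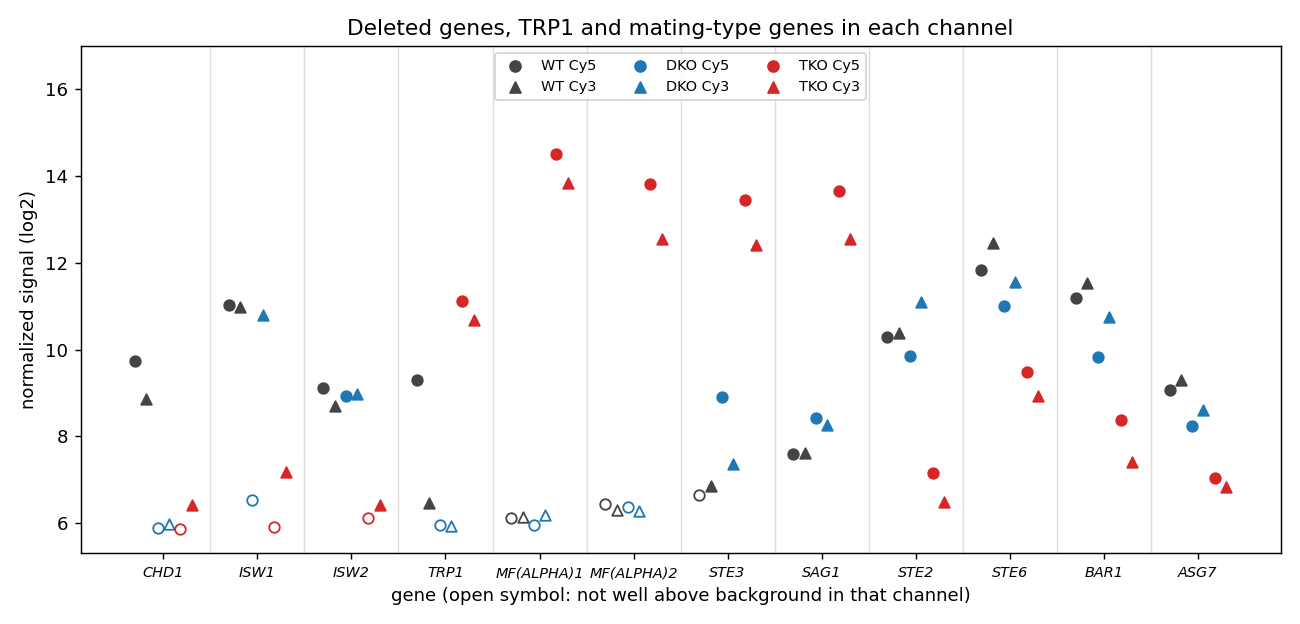
Normalized log2 signal (vertical axis) of the deleted genes, TRP1 and mating-type genes (horizontal axis) in each of the 6 channels; colour gives the genotype, circles are Cy5, triangles Cy3, and open symbols were not well above background. CHD1 was low in all 4 mutant channels, ISW1 was at 10.79 in the channel labelled DKO Cy3, and MF(ALPHA)1 exceeded 13 in TKO alone.

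The comparison of TKO with WT addresses what the joint loss of the 3 enzymes does to transcription. The mating type of the strains is not stated, and TKO differed from WT in mating genes. A difference in mating type and an effect of the deletions could therefore not be told apart. Genes of α cells rose in TKO: MF(ALPHA)1 and MF(ALPHA)2, which encode the α-factor pheromone, by log2 8.06 ± 0.275 and 6.80 ± 0.345, at least 220-fold and at least 109-fold. STE3, the receptor for a-factor, rose by 6.17 ± 0.434 and SAG1, the α-agglutinin, by 5.49 ± 0.318. The adjusted p of these 4 genes lay between 0.00493 and 0.0218. STE3 was not well above background in WT Cy5, so the size of its rise depends in part on the floor. Genes of a cells moved the other way. ASG7, an a-specific gene, fell by 2.25 (SE 0.218, adjusted p 0.0408), and HMRA1, which encodes the a1 repressor, fell by 2.76 (SE 0.265, adjusted p 0.0408).

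MATALPHA1 and HMLALPHA1, whose probes are annotated to both copies of the α1 activator gene, rose by 4.27 ± 0.341 and 4.25 ± 0.361, and YCR097W-A, a small reading frame near the silent HMR locus, by 4.02 ± 0.274. All 4 measured α-specific genes were called higher, and the list shifted up with a median of 6.49, or 6.47 with genes near background at their lower limit (camera adjusted p = 4.12e-10, adjusted p = 0.647 with an estimated correlation). All 7 measured a-specific genes were lower in both dyes, with a median of -2.25 (camera adjusted p = 1.92e-07, adjusted p = 0.647 with an estimated correlation). Of these 7, 1 was called over all genes and 7 adjusted over the list alone. All 7 were called lower in a fit of the 4 TKO and WT channels alone. STE2, the α-factor receptor, was at -3.51 ± 0.463 and BAR1, the protease that degrades α-factor, at -3.46 ± 0.467, with adjusted p of 0.0827 and 0.0838. Among 29 haploid and pheromone response genes, FIG1 (4.76 ± 0.401, at least 25.9-fold) and FIG2 (3.35 ± 0.338), both of which act in mating, were called higher over all genes, and 9 were higher and 2 lower adjusted over the list alone. Their list median was 0.50, from 0.95 in Cy5 and 0.05 in Cy3 (camera adjusted p = 4e-04, adjusted p = 0.647 with an estimated correlation). The pheromone median was 0.32 without WT Cy5, 0.11 without TKO Cy5 and 0.89 without TKO Cy3. The flocculin and adhesin list, which holds FIG2 and AGA1, had a median of 0.45 over 8 genes (camera adjusted p = 3.38e-05, adjusted p = 0.647 with an estimated correlation).

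**Figure D2:**
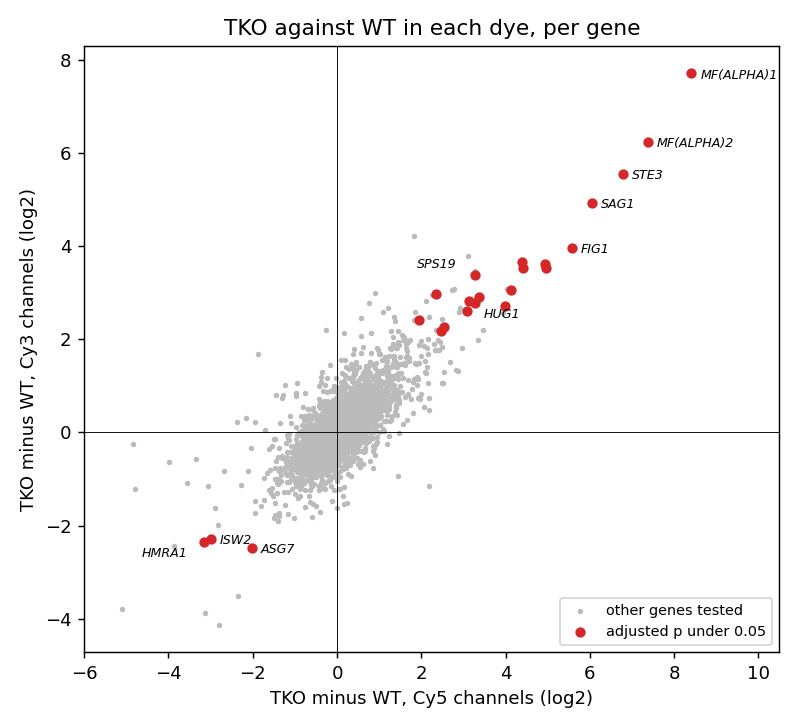
TKO minus WT difference of each tested gene in the Cy5 channels (horizontal axis, log2) against that in the Cy3 channels (vertical axis, log2); red points had an adjusted p under 0.05. The 23 called genes had the same direction in both dyes, with MF(ALPHA)1 and MF(ALPHA)2 farthest out, and the correlation across genes was 0.773.

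Genes of sporulation, which cells in rich medium keep silent, were higher in TKO than in WT. SPS2, a spore wall gene, rose by 2.84 ± 0.204 (adjusted p 0.0218, at least 5.61-fold), CDA1, a chitin deacetylase of the spore wall, by 2.40 ± 0.212 (adjusted p 0.0338), and SPS19, a peroxisomal enzyme made in sporulation, by 3.33 ± 0.28 (adjusted p 0.0327). Of 30 middle and late sporulation genes, 28 had positive values, 2 were called over all genes and 10 adjusted over the list alone. The list median was 0.75, and 0.63 with genes near background at their lower limit (camera adjusted p = 7.21e-11, adjusted p = 0.647 with an estimated correlation). Early meiotic and Ume6-repressed genes had a median of 0.43 over 34 genes (camera adjusted p = 1.92e-07, adjusted p = 0.647 with an estimated correlation), with 1 called over all genes and 12 higher and 1 lower adjusted over the list alone. SLZ1, a sporulation gene, was at 2.79 ± 0.302 (adjusted p 0.0549). HUG1, an inhibitor of ribonucleotide reductase induced by DNA damage, rose by 3.02 ± 0.258 (adjusted p 0.0327, at least 7.98-fold), and RNR3 was at 1.69 ± 0.356 (adjusted p 0.213). The 18 genes of the DNA damage response had a median of 0.49 (camera adjusted p = 0.000327, adjusted p = 0.647 with an estimated correlation). Without WT Cy5 the sporulation median was 0.46 and the DNA damage median 0.31, and without TKO Cy3 the latter was 0.24. The early meiotic median was 0.74 without WT Cy3. SPS2 and HUG1 lost their calls in 4 and 5 of 22 alternatives, and CDA1 and SPS19 in 7 and 6 of 23. Without mating genes, 4 of the 12 called genes still tested kept a call.

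Genes that glucose represses mostly had positive values too, with 1 of 32 called over all genes. ADH2, the alcohol dehydrogenase that consumes ethanol, rose by 2.18 ± 0.2 (adjusted p 0.0383), and POT1, a peroxisomal thiolase, was at 3.56 ± 0.992 (adjusted p 0.236). Of 32 glucose-repressed genes, 27 had positive values, and 5 were higher and 1 lower adjusted over the list alone, with a median of 0.62 (camera adjusted p = 2.74e-06, adjusted p = 0.647 with an estimated correlation). The general stress response had 57 of 59 genes above 0 and a median of 0.83 (camera adjusted p = 3.77e-09, adjusted p = 0.647 with an estimated correlation), with 0 members called. Its largest values were HSP32, whose probe is annotated to 3 genes of its family, at 2.95 ± 0.815, and GRE1 at 2.46 ± 1.33. Within the WT and TKO arrays the same stress list differed between the 2 cultures by -1.49 and -1.83 (Cy5 minus Cy3), more than it differed between the genotypes. Hexose transporters (median 0.87), aryl alcohol dehydrogenases (0.93), thiamine and vitamin B6 genes (0.43), and galactose and maltose genes (0.50) also shifted up, with camera adjusted p of 0.00029, 0.00194, 0.000651 and 0.00552, and each adjusted p = 0.647 with an estimated correlation. Without WT Cy5 the stress median was 0.42 and the glucose-repressed median 0.37, without TKO Cy5 they were 1.51 and 1.02, and without TKO Cy3 0.28 and 0.33. The hexose median was 0.42 without WT Cy3 and 0.34 without TKO Cy3. With dim genes at their lower limit the hexose and thiamine medians were 0.69 and 0.34. The probe of HXT17 is annotated to 4 genes and those of MAL12 and MAL32 to 2 each. Members of the hexose and of the galactose and maltose lists are thus not all independent signals. SNO1 and SNZ1, neighbouring vitamin B6 genes on the amino acid list, rose by 2.98 ± 0.2 (at least 7.46-fold) and 2.67 ± 0.262, with adjusted p of 0.0218 and 0.0408. That list of 54 genes had a median of -0.24, and its shift was not called (camera adjusted p = 0.101).

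Lower in TKO were iron uptake genes, with a median of -0.62 over 29 genes (camera adjusted p = 3.02e-05), and ribosome biogenesis genes, with -0.30 over 88 genes of which 85 were negative (camera adjusted p = 3.38e-05). Both had an adjusted p = 0.647 with an estimated correlation. FIT3 and FIT1, cell wall mannoproteins that retain iron, were at -3.01 ± 1.22 and -2.56 ± 1.04, mostly from Cy5 (-4.80 and -4.85, against -1.21 and -0.26 in Cy3). The iron median was -0.30 without WT Cy5 and -0.40 without TKO Cy5. Adjusted over the list alone, 3 iron genes were called lower. Histones (median -0.33, HTB2 at -1.03 ± 0.308), phosphate starvation genes (-0.67), ergosterol and lipid genes (-0.35) and G1/S genes (-0.24) were also called lower, with camera adjusted p of 0.00796, 0.0283, 0.00347 and 0.00907 and again an adjusted p = 0.647 with an estimated correlation. The histone median was -0.74 in Cy5 and -0.0073 in Cy3. It was -0.059 without WT Cy5, -0.73 without WT Cy3, -0.10 without TKO Cy5 and -0.62 without TKO Cy3. The phosphate median was -0.27 without WT Cy5 or TKO Cy3 and -1.13 without WT Cy3. The heat shock, PAU and subtelomeric COS and YRF1 lists shifted up by medians of 0.24, 0.16 and 0.42 (camera adjusted p 0.0106, 0.0345 and 0.00692). Each had an adjusted p of 0.647 or 0.656 with an estimated correlation. Cytosolic ribosomal protein genes had a median of 0.02 over 136 genes (camera adjusted p = 0.349), and 14 housekeeping reference genes one of -0.04 (camera adjusted p = 0.873).

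Of the deleted genes, ISW2 fell by 2.64 in TKO (SE 0.233, adjusted p 0.0338), while CHD1 was at -3.16 ± 0.368 (adjusted p 0.0652) and ISW1 at -4.45 ± 1 (adjusted p 0.224). None of these genes was well above background in TKO Cy5, so the sizes depend in part on the floor. Among markers, TRP1 was at 3.02 ± 0.7, URA3 at -1.61 ± 0.228, ADE2 at -1.35 ± 0.264, HIS3 at -0.27 ± 0.273 and LEU2 at -0.27 ± 0.21, none of them called. In total limma called 23 genes, 20 higher and 3 lower, and 882 had an unadjusted p under 0.05. In both dyes, 176 genes were at least 2-fold higher and 45 at least 2-fold lower. WT and TKO shared a difference between Cy5 and Cy3 (r = 0.804 across genes) that DKO lacked (r = -0.119 with WT), and a single dye term leaves this mismatch in the residual. In a limma fit of the 4 TKO and WT channels alone 1196 genes were called, 635 higher and 561 lower. Among them were CHD1 (adjusted p 0.000235), ISW1 (3.07e-05) and 38 stress genes. The markers URA3 (0.00035), TRP1 (0.00252) and ADE2 (0.00269) were called there too, HIS3 and LEU2 not. Leaving out either DKO channel gives this same fit for TKO vs WT, since a lone DKO channel adds nothing to the residual. Without either DKO channel the count was the same 1196, without WT Cy5 it was 7, without TKO Cy5 3 and without TKO Cy3 8. MF(ALPHA)1 was called in each of these fits, at 7.65 or more. ISW2 and SPS19 lost their calls without WT Cy5 or either TKO channel, and ADH2 without any 1 of the WT and TKO channels (adjusted p up to 0.202, 0.161 and 0.329). Without the filter on dim probes 1 gene was called. When all arrays had to pass it was 3, with only 13 of the 23 genes still tested, since genes dim in 1 genotype drop out. Scaling to the 75th percentile gave 73, with the median of all genes moved from -0.0666 to 0.0606, and scaling to the median gave 61, and under the scalings run on lists (quantile and 75th percentile) no called list changed direction. With the 75th percentile the heat shock (median 0.27, camera adjusted p 0.2), PAU (0.17, 0.213) and G1/S lists (-0.09, 0.0521) lost their calls, the medians of the former pair being no smaller than before. Without WT Cy5, 13 lists were called. Galactose and maltose (median 0.48) and ergosterol genes (-0.34) lost the call with medians close to before, and histones (-0.059), phosphate (-0.27), ribosome biogenesis (-0.16), heat shock (0.034) and G1/S genes (-0.13) with medians nearer to 0. The PAU (-0.14), COS and YRF1 (-0.03) and thiamine (-0.0022) medians then changed sign. Without WT Cy3 the heat shock, PAU, COS and YRF1, and thiamine medians were 0.47, 0.54, 0.87 and 0.70. Not called without TKO Cy5 were histones (median -0.10, camera adjusted p 0.148), PAU (0.054, 0.355) and COS and YRF1 genes (0.48, 0.0674). Not called without TKO Cy3 were phosphate (-0.27, 0.15), ribosome biogenesis (-0.17, 0.0785), heat shock (0.12, 0.0768), galactose and maltose (0.15, 0.195) and ergosterol genes (-0.25, 0.0941), and the PAU median was then 0.29.

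The comparison of DKO with WT addresses the loss of Chd1 and Isw1 with Isw2 present, and it rests on a channel in which ISW1 transcript was found. With both DKO channels, 0 genes passed in limma, the smallest adjusted p was 0.0704, and 1566 genes had an unadjusted p under 0.05, 850 higher and 716 lower. The 5 lowest values among genes with 1 direction in both dyes follow. TMA10, a ribosome-associated stress protein, was at -5.35 ± 0.549, MPC3, a subunit of the mitochondrial pyruvate carrier, at -4.98 ± 1.13 (-2.72 in Cy5, -7.24 in Cy3), RGI1, which acts in respiratory growth, at -4.61 ± 0.577, HXK1, a hexokinase repressed by glucose, at -3.70 ± 0.538, and YKR075C at -3.67 ± 0.278. The highest such values were those of RTA1, a membrane protein of sterol drug resistance (3.54 ± 0.222), PRM7 (3.05 ± 0.535), YDL187C (2.42 ± 0.217), GSC2, a glucan synthase (2.41 ± 0.211), and BSC1 (2.36 ± 0.311). The adjusted p of these 10 genes was 0.0704 to 0.091.

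Gene lists shifted down in DKO around stress and mitochondria. The general stress response had a median of -1.42 over 59 genes (camera adjusted p = 3.26e-08, adjusted p = 0.923 with an estimated correlation), and 11 members were lower adjusted over the list alone. The difference was -0.38 in Cy5 and -2.47 in Cy3, and within the WT array the list differed by -1.49 between the 2 cultures. HXK1 belongs to this list, as does ALD4, a mitochondrial aldehyde dehydrogenase (-3.64 ± 0.747, and -2.32 without the channel labelled DKO Cy3). Heat shock genes (median -0.63, 10 lower and 2 higher adjusted over the list alone) included HSP42 at -2.77 ± 0.454 and HSP78 at -1.76 ± 0.236, both also on the general stress list. Respiratory chain and TCA cycle genes (-0.37) included CYT1, cytochrome c1, at -2.53 ± 0.342 and CIT1, citrate synthase, at -2.48 ± 0.462. Mitochondrial ribosome genes had a median of -0.28. Without the channel labelled DKO Cy3 these 3 medians were -0.25, -0.045 and -0.17, and the stress median was -0.26. Without DKO Cy5 the stress and respiratory medians were -2.43 and -0.70. Without WT Cy3 the heat shock and respiratory medians were -0.40 and -0.11. Each of these 3 lists had a camera adjusted p of 0.00122 and an adjusted p = 0.923 with an estimated correlation. Proteasome genes, the targets of Rpn4, were at a median of -0.41, and of -0.26 without DKO Cy3, with 34 of 35 negative (camera adjusted p = 3.02e-05, adjusted p = 0.923 with an estimated correlation).

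The flocculin and PAU lists shifted up, whereas the cell wall integrity list was not called (camera adjusted p = 0.999), with 12 positive and 12 negative members and CWP1 at -2.94 ± 0.266. Flocculins and adhesins had a median of 1.09, with all 8 genes positive and 5 higher adjusted over the list alone. Among them were FLO5 (1.58 ± 0.21) and FLO10 (1.47 ± 0.197). FLO5 lies on chromosome VIII, whose genes were higher in DKO Cy5 than in DKO Cy3. The seripauperin (PAU) family, mostly subtelomeric cell wall genes with shared probes, had a median of 0.70 with 25 of 30 positive, and of 0.34 without WT Cy5 and 0.45 without DKO Cy5. Camera adjusted p was 0.000235 and 0.000399 for these lists, and both had an adjusted p = 0.923 with an estimated correlation. Phosphate starvation (median -0.69), sulfur and methionine (-0.26) and iron genes (-0.24) shifted down, with camera adjusted p of 0.031, 0.0194 and 0.0396 and an adjusted p = 0.923 with an estimated correlation. PHM8, a phosphatase of phosphate starvation that is also on the general stress list, was at -1.97 ± 0.421, MUP1, a methionine permease, at -2.01 ± 0.396 and HMX1, a heme oxygenase, at -3.25 ± 0.422. Without DKO Cy3 these genes were at -1.36, -2.42 and -2.53. PHM8 and HMX1 thus moved nearer to 0, whereas the 3 list shifts grew. These 3 shifts lay in the Cy5 channels: the Cy3 medians were 0.03, 0.02 and 0.01, and without DKO Cy5 the medians were 0.002, -0.034 and -0.11 (camera adjusted p 0.919, 0.276 and 0.287). Without DKO Cy3 they were -1.16, -0.42 and -0.43. None of the 3 was called without WT Cy5 either, with medians of -0.29, 0.015 and -0.043 (camera adjusted p 0.314, 0.173 and 0.634), and without WT Cy3 the sulfur and iron medians were -0.51 and -0.57. The phosphate list was also not called with 75th percentile scaling (0.0524), nor the iron list with processed signals (0.0558). Conversely the heat shock, respiratory and mitochondrial ribosome lists were not called without DKO Cy3 (camera adjusted p 0.064, 0.158 and 0.0659).

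Chromosome VIII genes, a pattern singled out after its values were seen, were higher in DKO Cy5 than in DKO Cy3, with a median difference of 0.784 over 260 genes and 96.54% of them positive. The medians of the other 15 chromosomes lay between -0.118 and 0.0552. On chromosome VIII the difference was -0.00309 in WT and -0.0325 in TKO. Against WT it was 0.798 in the Cy5 channel and 0.000993 in the channel labelled DKO Cy3.

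**Figure D3:**
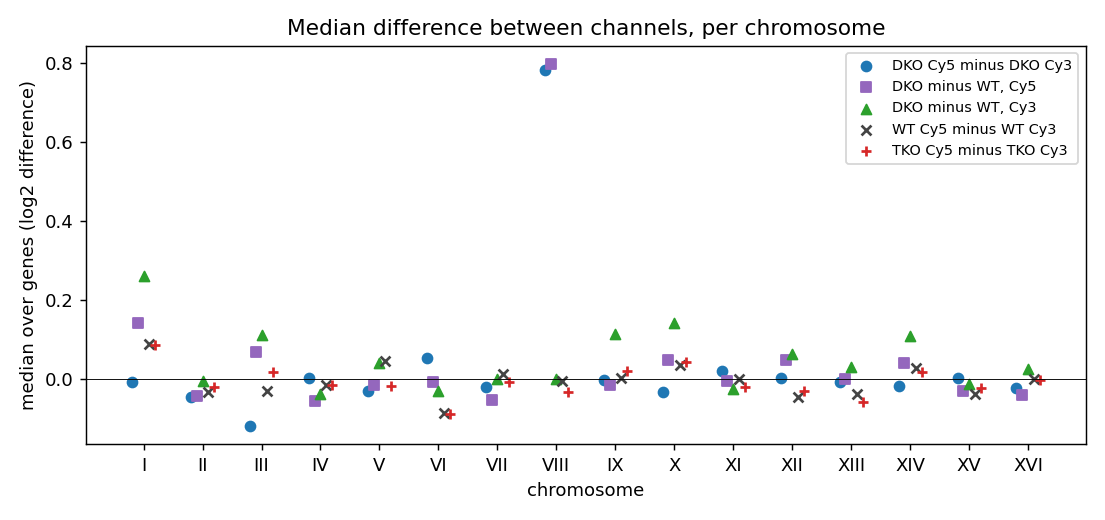
Median log2 difference between 2 channels over the genes of each chromosome (vertical axis) against chromosome (horizontal axis); symbols give the pair of channels. Chromosome VIII stood at 0.784 for DKO Cy5 minus DKO Cy3 and at 0.798 for DKO minus WT in Cy5, and near 0 for the other 3 pairs.

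CHD1 was at -3.37 ± 0.368 in DKO against WT (adjusted p 0.0704, at least 7.29-fold lower). ISW1 was at -4.49 in Cy5, where DKO was at background, and -0.17 in Cy3, and ISW2 at 0.05 ± 0.233, a sign that turned under 75th percentile scaling (-0.09) and without DKO Cy3 (-0.005) or WT Cy3 (-0.24). ADE2 was at -1.52 ± 0.264, TRP1 at -1.93 ± 0.7 (at least 2.71-fold lower, being near background in DKO), LEU2 at 0.96 ± 0.21, HIS3 at 0.46 ± 0.273 and URA3 at -0.62 ± 0.228. The count of 0 rose to 1232 without DKO Cy3 (765 higher, 467 lower, 157 on chromosome VIII), to 2043 without DKO Cy5, and to 3 without either TKO channel. It was 73 with processed signals, 320 with 75th percentile scaling (58.8% higher) and 475 with median scaling (74.3% higher), which moved the median of all genes from 0.0242 to 0.2. Without DKO Cy3 a single DKO channel is left, assumed to vary like the others, and RTA1 (3.63 ± 0.241), GSC2 (2.65 ± 0.198), TMA10 (-4.61 ± 0.409), MPC3 (-2.82 ± 0.219) and HXK1 (-2.71 ± 0.198) were then among the genes called. So were CHD1 and ISW1, which were at background in DKO Cy5. In that fit, 21 of 30 PAU genes were higher, 15 of 22 phosphate genes were lower, and of 59 stress genes 17 were lower and 7 higher.

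The comparison of TKO with DKO addresses what the loss of Isw2 adds, with the same limit on the DKO label and with strains that also differ in mating genes. ISW2 itself fell by 2.69 (SE 0.233, adjusted p 0.0274), a size that depends in part on the floor, since TKO Cy5 was not above background. The α-specific genes rose again: MF(ALPHA)1 by 8.12 ± 0.275 (at least 215-fold), MF(ALPHA)2 by 6.86 ± 0.345 (at least 105-fold), STE3 by 4.78 ± 0.434 and SAG1 by 4.75 ± 0.318. Also among the 8 highest were TMA10 (5.76 ± 0.549), MPC3 (5.70 ± 1.13, and 3.54 without DKO Cy3), HXK1 (5.35 ± 0.538) and TRP1 (4.95 ± 0.7, at least 22-fold). STE2 (-3.65 ± 0.463), the a-factor gene MFA2 (-2.75 ± 0.495) and HMRA1 (-2.86 ± 0.265) fell. So did PRM7 (-3.58 ± 0.535), the ammonium permease MEP2 (-3.46 ± 0.605), RTA1 (-3.16 ± 0.222) and the drug exporter SGE1 (-2.66 ± 0.2). The adjusted p of the genes named here was 0.00475 to 0.0493.

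The general stress, heat shock, glucose-repressed, respiratory and hexose transporter lists shifted up in TKO relative to DKO. The general stress list had a median of 2.44 with 58 of 59 genes positive (camera adjusted p = 5.39e-17, adjusted p = 0.751 with an estimated correlation). Of its members 13 were called higher over all genes and 43 adjusted over the list alone. Among them were CYC7, a cytochrome c isoform (4.27 ± 0.573), GSY1, a glycogen synthase (4.08 ± 0.367), and ALD4 (3.79 ± 0.747, and 2.47 without DKO Cy3). The list median was 1.05 in Cy5 and 3.51 in Cy3. Between the 2 TKO cultures the list differed by -1.83 (Cy5 minus Cy3), against 0.29 between the channels labelled DKO. Heat shock genes (median 0.77, 6 called) included HSP42 (3.27 ± 0.454), HSP82 (2.75 ± 0.479), HSP78 (2.15 ± 0.236) and SIS1 (1.64 ± 0.197). HSP42 and HSP78 are also on the general stress list. Glucose-repressed genes (0.72, 5 called) included ALD6 (3.33 ± 0.329), REG2 (2.73 ± 0.514, and 1.81 without DKO Cy3) and CRC1 (1.53 ± 0.275). Respiratory genes (0.58, 5 called) included CYT1 (2.65 ± 0.342), CIT1 (2.51 ± 0.462), MDH1 (1.97 ± 0.228) and NDE1 (1.73 ± 0.207). Among hexose transporters (0.78, or 0.64 at their lower limits, 3 called), HXT6 and HXT7, whose probes are annotated to both, rose by 3.28 ± 0.373 and 3.07 ± 0.296 and HXT4 by 1.34 ± 0.199. Without the channel labelled DKO Cy3 the medians were 1.05 (stress), 0.47 (heat shock), 0.36 (glucose-repressed), 0.24 (respiratory) and 0.45 (hexose), the last being 0.34 without TKO Cy3. Without DKO Cy5 the glucose-repressed and hexose medians were 1.12 and 1.35. The hexose median was 0.12 in Cy5 and 1.44 in Cy3. Camera adjusted p for the last 4 lists was 1.43e-05, 1.05e-05, 1.34e-05 and 0.00112, and each had an adjusted p = 0.751 with an estimated correlation. Proteasome (0.49), mitochondrial ribosome (0.29) and galactose and maltose genes (0.75) shifted up with 0 members called, with medians of 0.29, 0.18 and 0.14 without DKO Cy3. The proteasome median was 0.31 without TKO Cy3, and the galactose and maltose median was 1.52 without DKO Cy5 and 0.39 without TKO Cy3. The 3 lists were called at camera adjusted p of 1.05e-05, 0.000585 and 0.00787 and again an adjusted p = 0.751 with an estimated correlation.

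Sporulation genes were higher than in DKO as well. Early meiotic genes had a median of 0.43 with 5 called, including SLZ1 (3.58 ± 0.302, at least 11-fold), SPS19 (2.51 ± 0.28), and the arginine catabolic genes CAR1 (2.08 ± 0.274) and CAR2 (1.5 ± 0.218). Middle and late sporulation genes had a median of 0.65, or 0.56 with dim genes at their lower limit, with 4 called, SPS2 (2.74 ± 0.204, at least 5.47-fold), CDA1 (1.77 ± 0.212), CDA2 (1.25 ± 0.171, at least 1.89-fold) and MPC54 (1.13 ± 0.226). The early meiotic median was 0.19 in Cy5 and 0.69 in Cy3, and without the channel labelled DKO Cy3 the medians were 0.13 and 0.30. Without DKO Cy5 the early meiotic median was 0.76. Camera adjusted p was 7.96e-05 and 1.41e-05, with an adjusted p = 0.751 with an estimated correlation for both. The 4 α-specific genes had a median of 5.82 (5.75 at their lower limits) and the 7 a-specific genes of -2.06, with 4 and 6 called, among the latter BAR1 (-2.39 ± 0.467) and STE6, the a-factor exporter (-2.06 ± 0.338). Pheromone response genes had a median of 0.54 (1.21 in Cy5, 0.33 in Cy3), and of 1.01 without DKO Cy3 and 1.19 without TKO Cy3, with 6 higher and 2 lower, among them FIG1 (4.33 ± 0.401), FIG2 (2.75 ± 0.338), FUS1 (2.73 ± 0.378) and PRM1 (2.60 ± 0.332). Camera adjusted p for the 3 mating lists was 1.02e-05, 0.00013 and 0.0014, each with an adjusted p = 0.751 with an estimated correlation. DNA damage genes had a median of 0.37 (camera adjusted p = 0.0353, adjusted p = 0.751 with an estimated correlation), with HUG1 (2.07 ± 0.258) and MAG1 (1.62 ± 0.277) higher and SML1 lower (-1.36 ± 0.261).

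Ribosome biogenesis, G1/S, ergosterol, amino acid and PAU lists shifted down in TKO relative to DKO, while cytosolic ribosomal protein and G2/M lists were not called (camera adjusted p 0.276 for both). Ribosome biogenesis genes had a median of -0.55 (-0.24 in Cy5 and -0.78 in Cy3), with 6 of 88 lower over all genes and 19 adjusted over the list alone, including RPA12, a subunit of RNA polymerase I (-1.79 ± 0.338), DBP8 (-1.42 ± 0.247), TIF6 (-1.34 ± 0.222) and PWP2 (-1.15 ± 0.219). G1/S genes had a median of -0.29 (-0.20 in Cy5, -0.58 in Cy3), and of -0.58 without DKO Cy5 and -0.14 with 75th percentile scaling, with 7 of 39 lower over all genes and 14 adjusted over the list alone, including the cyclins PCL1 (-2.25 ± 0.309) and CLN1 (-1.96 ± 0.232), the transcription factor HCM1 (-1.98 ± 0.173) and RNR1 (-1.87 ± 0.303). Ergosterol and lipid genes (-0.55, with ELO3 at -1.46 ± 0.246 and HMG2 at -0.99 ± 0.186), amino acid genes (-0.34, with CPA1 at -1.74 ± 0.185 and THR1 at -1.52 ± 0.293) and PAU genes (-0.54, with PAU11, whose probe is annotated to 4 genes, at -1.42 ± 0.261) also shifted down. Without DKO Cy3 the ribosome biogenesis median was -0.28, the ergosterol median -0.34 and the amino acid median -0.11. The amino acid median was -0.56 without DKO Cy5 and -0.21 without TKO Cy3, and the PAU median -0.30 without DKO Cy5. Camera adjusted p of these 5 lists was 1.34e-05, 0.00583, 0.00148, 0.0339 and 0.0353, and with an estimated correlation each had an adjusted p of 0.751 or 0.752. Among cell wall genes, whose list was not called (camera adjusted p = 0.501), PIR3 (3.33 ± 0.219) and CWP1 (3.07 ± 0.266) were higher and YPS1 (-1.58 ± 0.201) and GSC2 (-1.21 ± 0.211) lower. Flocculins went both ways, with FLO5 (-1.18 ± 0.21) and FLO9 (-1.01 ± 0.183) lower and AGA1 (2.30 ± 0.352), which acts in mating, higher (camera adjusted p = 0.483). DBP8, THR1 and FLO5 lie on chromosome VIII, whose genes were higher in DKO Cy5 than in DKO Cy3. Among markers, LEU2 (-1.24 ± 0.21) and CAN1 (-1.64 ± 0.259) fell. HIS3 was at -0.73 ± 0.273 and URA3 at -1.0 ± 0.228, not called. CHD1 (0.21 ± 0.368) and ADE2 (0.17 ± 0.264) were not called and changed sign under some settings, and ISW1 was at -2.12 ± 1. The ISW1 value averages -0.62 in Cy5, where both strains were at background, and -3.61 in Cy3, where the channel labelled DKO had ISW1 transcript, and was -0.29 without that channel.

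In total limma called 467 genes, 179 higher and 288 lower (38.3% higher), 423 of them at least 2-fold, and 1997 had an unadjusted p under 0.05. Of the 467 genes, 32 lay on chromosome VIII and 14 had shared probes. The share that was higher depended on scaling: 53.8% of 669 genes with the 75th percentile and 29.4% of 941 genes with the median, which moved the median of all genes from -0.0635 to -0.193. The fit of the 4 TKO and DKO channels alone called 238 genes. Leaving out either WT channel gives this same fit for TKO vs DKO and is no separate check. Without TKO Cy5 or Cy3 the count was 4 or 5, and without DKO Cy5 or Cy3 it was 2802 or 1304. Each lone channel was assumed to vary like the others. HXK1 kept its call without either DKO channel, at 6.34 and 4.36, and lost it without TKO Cy5 (adjusted p 0.0662) or TKO Cy3 (0.133). The amino acid list was not called without DKO Cy3 (camera adjusted p 0.522) or TKO Cy3 (0.227), PAU genes not without DKO Cy5 (0.245) or TKO Cy3 (0.054), galactose and maltose genes not without DKO Cy3 (0.145), and DNA damage genes not without DKO Cy3 (0.208) or TKO Cy5 (0.0529). With processed signals the amino acid (0.0502) and PAU lists (0.0599) were not called.

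In both dyes and both mutants, 15 genes were at least 2-fold above WT and 1, CHD1, at least 2-fold below. An overlap of called genes was not counted, since 0 genes were called for DKO. The 15 were chosen after their values were seen and included SNO1 (2.98 ± 0.2 in TKO, 2.02 ± 0.2 in DKO), SNZ1 (2.67 ± 0.262 and 1.45 ± 0.262), ADH2 (2.18 ± 0.2 and 1.46 ± 0.2), GSC2 (1.19 ± 0.211 and 2.41 ± 0.211) and DAL4, an allantoin permease (1.69 ± 0.204 and 1.35 ± 0.204). At an unadjusted p under 0.05, 152 genes were higher in both mutants against 66.2 expected from the product of the shares, and 85 lower against 54.3. Part of that overlap may come from the shared WT channels. Across genes, which are not independent replicates, the fold changes of the mutants against WT correlated at r = 0.0948 (rho = 0.0951). Their covariance was 0.0363, against 0.0411 in 100 simulations of unchanged groups that shared the WT channels. The simulated r was 0.505, and 66.8% of simulated genes had the same sign in both mutants, against 54.4% observed. The simulated noise took the pooled spread of the fit, which holds the DKO mismatch, rather than that of the WT channels. Within dyes r was 0.467 in Cy5 and -0.14 in the Cy3 channels, where the DKO label is contradicted. Pairs that share no WT channel gave -0.129 (TKO Cy5 with DKO Cy3) and 0.196 (TKO Cy3 with DKO Cy5).

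**Figure D4:**
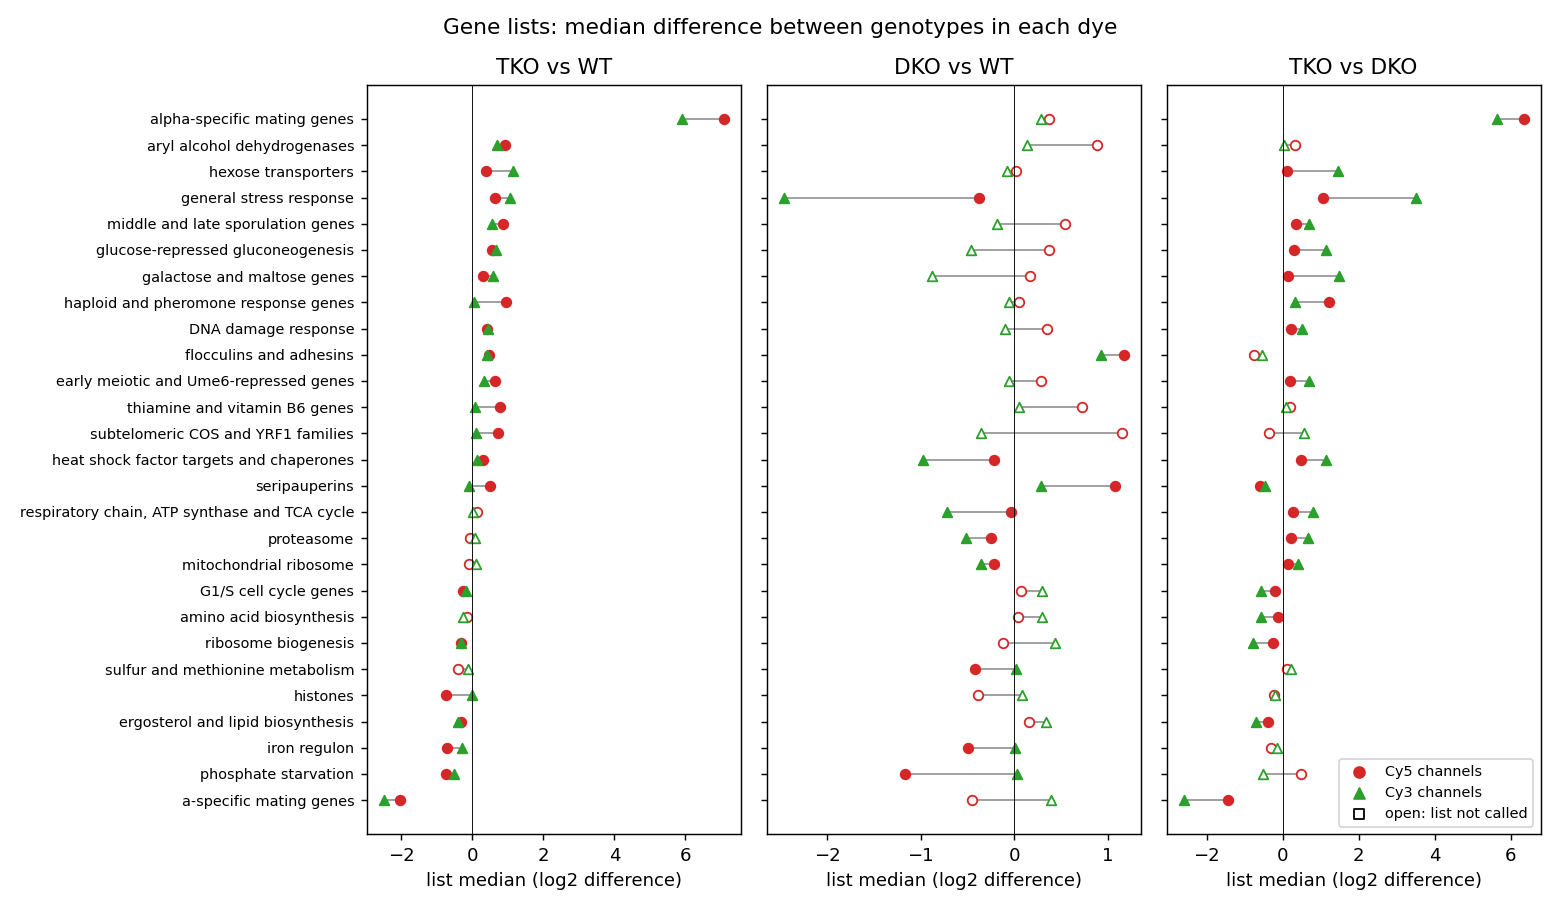
Median log2 difference of 27 gene lists (vertical axis) in the Cy5 (circles) and Cy3 (triangles) channels for each comparison; filled symbols mark lists called by camera at the preset correlation. The general stress list stood at -0.38 in Cy5 and -2.47 in Cy3 for DKO against WT, and the α-specific list at 7.08 and 5.89 for TKO against WT.

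The 2 cultures of a genotype differed by a median absolute log2 of 0.35 in WT, 0.225 in DKO and 0.309 in TKO, dye effect included. At least 2-fold differences were found in 511, 196 and 468 genes. In WT and TKO the Cy3 culture had more transcript of stress genes, chosen after their values were seen: ALD3 differed by -5.88 and -6.21 (Cy5 minus Cy3), HSP12 by -5.83 and -4.58 and CTT1 by -4.99 and -5.45. In DKO the same genes differed by 0.46, 1.02 and 0.71. Ribosome biogenesis genes went the other way, with medians of 0.63 in WT and 0.63 in TKO, and 0.09 in DKO.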

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

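Alternatives chosen only after the data were seen were those without chromosome VIII genes, without mating genes, and without the DKO Cy3 channel together with chromosome VIII genes. Of the values that answer a comparison, 76 stayed within 1.5 times or within their spread. Counts of called genes or lists rose from 0 or by over 1.5 times in 24 cases and fell by as much in 16, 13 other values moved and 1 reversed. Of the named genes and lists, 2714 stayed, 429 lost a call, 129 gained one and 12 reversed. Calls that held under all alternatives run were those of MF(ALPHA)1 against WT and DKO and of MF(ALPHA)2 against DKO. For TKO vs WT, 37 genes were called without loess, 73 with 75th percentile scaling, 61 with median scaling, 1 without a filter and 3 with all arrays above background, against 23. Counts were 4 without mating genes, where 12 of the 23 genes were still tested, 1196 with only its 4 channels, 1214 without DKO Cy3 and chromosome VIII, and 3 to 1196 with each channel left out in turn. For DKO vs WT, 73 were called with processed signals, 21 without loess, 320 and 475 with 75th percentile and median scaling, and 2 without the dye term, against 0. Counts were 3 with only its 4 channels, 1081 without DKO Cy3 and chromosome VIII, and 0 to 2043 with each channel left out. For TKO vs DKO, 941 were called with median scaling, 253 without the dye term, 238 with only its 4 channels, 1135 without DKO Cy3 and chromosome VIII, and 4 to 2802 with each channel left out, against 467. Without the dye term TKO vs WT gave 31. Leaving out a channel of the genotype not compared gives the same fit of genes as only the 4 channels compared. The tallies of alternatives for genes therefore hold that fit repeatedly. The rise on leaving out a DKO channel follows from the fit, since the mismatch between the Cy5 minus Cy3 differences of DKO and those that WT and TKO share then no longer enters the residual, and a lone channel is assumed to vary like the others. The estimated correlation gave 0, 0 and 0 gene list shifts against 22, 10 and 19. With a residual df of 2, its smallest camera adjusted p was 0.647, 0.923 and 0.751. Even the α-specific list, with a median of 6.49 and all 4 genes called for TKO vs WT, was at 0.647. That test could thus hardly call any list and cannot decide whether correlation accounts for the shifts. The 75th percentile gave 20 shifts for DKO vs WT, and leaving out channels gave 13 to 27, 11 to 16 and 19 to 21. HIS3 turned to 0.00902 for TKO vs WT with the 75th percentile, and ranged from -0.66 to 0.13 with channels left out. ISW2 for DKO vs WT turned to -0.092 with the 75th percentile and to -0.0055 without DKO Cy3 and chromosome VIII, and ranged from -0.24 to 0.34. CHD1 for TKO vs DKO turned to -0.087 with the 75th percentile and -0.31 with the median, and ranged from -0.27 to 0.69. ADE2 for TKO vs DKO ranged from -0.039 to 0.38. None of these 4 was called. The subtelomeric COS and YRF1 median for TKO vs WT ranged from -0.0325 to 0.869 and reversed without WT Cy5. The correlation of fold changes was -0.129 for TKO Cy5 against DKO Cy3. With processed signals CHD1 was at -7.07 and -6.75 (DKO Cy5 and Cy3 minus WT) and -7.11 and -5.20 (TKO), ISW1 at -8.41 and -0.027 (DKO) and -9.08 and -5.12 (TKO), and ISW2 at -5.92 and -4.72 (TKO). CHD1 in both DKO channels and TKO Cy5, ISW1 in DKO Cy5 and TKO Cy5, and ISW2 in TKO Cy5 were not above background, so these differences depend on the floor and give no size of the change. The WT difference within the array was 0.426 and the chromosome VIII median 0.924 with processed signals, and that median was 0.889 with offset 0. For the other changes the cause was not tested. Channels of the same replicate number were checked for pairing: their Cy5 minus Cy3 differences correlated at 0.804 for WT and TKO, -0.119 for WT and DKO and -0.0691 for TKO and DKO, so the numbers did not pair all samples. The comparison by the authors' ratio table was not run, because its columns hold other channel pairs than their headings name. Signal over background ranged from 9.25 in DKO Cy5 to 31.3 in WT Cy3, and its effect on calls among dim genes was not tested.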

Other observations

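Mitochondrially encoded genes, chosen after their values were seen, differed among the genotypes. Of 8 measured genes, 7 were lower in DKO than in WT in both dyes, and medians were -1.15 for DKO vs WT, 0.51 for TKO vs WT and 1.53 for TKO vs DKO. DKO minus WT was -0.57 in Cy5 and -1.40 in Cy3, and the 2 cultures of WT and of TKO differed by -0.795 and -0.883. COB, cytochrome b, was at 4.27 ± 0.42 in TKO vs DKO (adjusted p 0.0274) and at -2.45 in DKO vs WT (adjusted p 0.0704). COX1 (2.59 ± 0.359), COX3 (1.77 ± 0.296) and AI2 (1.69 ± 0.256), a maturase of a COX1 intron, were also called higher in TKO vs DKO. Labelling was primed by oligo-dT, whereas yeast mitochondrial transcripts carry no poly(A) tails.

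All tests below were chosen after the result was seen, except those of chromosome VIII segments and of haploid-specific genes.

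The channels labelled DKO differed in ISW1 and along chromosome VIII. Wild-type RNA mixed into the Cy3 channel is argued against by CHD1, which differed by 0.0885 (Cy3 minus Cy5) and stayed near background in both. A dye or normalization effect on chromosome VIII probes is argued against by the TKO array, with a median of -0.0325 over the same genes. An extra copy of chromosome VIII in the DKO Cy5 culture is a candidate explanation. Each of 4 segments of 65 genes was shifted, the lowest by 0.653. With 96.54% of the chromosome's genes already seen to be positive, an unshifted segment was unlikely in advance, so the segments add little support. A chd1 single mutant as the channel labelled DKO Cy3, and an ISW1 disruption that leaves the probed region transcribed, may each explain its ISW1 signal, and both stay open and untested.

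WT and TKO shared their Cy5 minus Cy3 differences, and DKO did not. A dye bias of the probes is argued against by the correlation of -0.119 between the WT and DKO differences. A labelling or hybridization difference between arrays that varies from sequence to sequence is argued against by the spike-in RNAs. Their ratios differed between the WT and DKO arrays with an SD of 0.0579, against 0.849 for genes. This SD cannot show a shift common to all sequences. Mean spike-in differences, DKO minus WT, were -0.179 in Cy5 and 0.518 in Cy3. For TKO minus WT they were 0.0544 and 0.675, so the Cy3 shift was found in TKO too and did not set DKO apart. Another growth state of the Cy3 than of the Cy5 cultures stays open: the stress list differed by -1.49 in WT and ribosome biogenesis went the other way, but these genes show the pattern and so lend it no support. Densities at harvest are not stated in the labels, and no biological explanation was tested.

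TKO showed mating genes of α cells and WT and DKO mainly those of a cells. The α-specific gene STE3 was at log2 8.913 in DKO Cy5, between 6.658 in WT Cy5 and 13.45 in TKO Cy5. Expression of both mating types through lost silencing of the silent cassettes would turn off haploid-specific genes, and is argued against by 8 such genes with a median of -0.251, from -0.562 to 0.376. An α strain as TKO and a strains as WT and DKO stays open: 11 of 11 α- and a-specific genes went that way, but they are the genes that show the pattern and so lend it no support. An effect of the deletions on mating genes stays open and untested as well.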
